A study of Mus musculus with 9 samples.

How the data were processed

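RNA from 9 cultures of NIH 3T3 mouse fibroblasts was measured on 1-colour Affymetrix arrays, with 3 cultures per group carrying a control, Ube2m or Ube2f shRNA. Per the labels, total RNA was extracted with Trizol 5 days after transduction, and biotin-labelled cRNA was made from 6 ug of total RNA. The deposited values were read as intensity, the linear signal of each probe set, which the submitters' processing notes attribute to MAS5, an algorithm that sets perfect-match against mismatch probes. Its version, scaling settings and detection calls are not given in the sources used here. On every array the mean signal after leaving out the top and bottom 2% of the 45101 probe sets was 500, so that each array had been scaled by 1 factor. Such scaling leaves any difference in the shape of the distribution between arrays in place, and MAS5 signals vary strongly near the background, which is why a constant was added and low signals were removed. For arrays no depth is counted, and the number of arrays limits the precision.

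Signals were analysed as log2(signal + 16). The 64 control probe sets, the 932 probe sets assigned to several genes and the 9160 without a gene name were left out, the last being analysed separately in the closing section. Gene names came from the probe table used here and were looked up in a mouse reference, which listed 34741 of the 34945 probe sets with 1 gene, and no name was changed. Of the probe sets of each of 18193 genes, the one with the highest mean over the 9 arrays was kept. Genes were tested if their mean log2 value reached the median of all probe sets other than controls (6.12, a signal of 53.8), which left 10613. No positions in the genome are given, since the reference served for names only.

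A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, and eBayes with an intensity trend, prior degrees of freedom 6.55). The 3 comparisons were, Ube2m shRNA against control, Ube2f shRNA against control and Ube2m shRNA against Ube2f shRNA. All p-values are two-sided and adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05, and SE is the standard error of the log2 fold change in that fit. For a single value, an exact permutation test of 3 against 3 arrays cannot give a p under 0.1, so no such test was used. Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which tests whether a list's genes move one way on balance and compares them with no other genes. Camera compares a list with all other genes tested. Preset-correlation calls also appeared when arrays were grouped wrongly, so they are weak evidence unless the other tests also pass. With an estimated correlation 3, 0 and 2 lists passed in the 3 comparisons, against 6, 3 and 7 with the preset one and 4, 4 and 9 with fry. Each list that passed with an estimated correlation also passed by fry. The estimated correlation was -0.0088 for interferon-stimulated genes and -0.053 for skeletal muscle genes, both under the preset 0.01. Correlation between genes therefore does not account for the calls these lists lost in that test.

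The comparisons, tests, 26 gene lists, alternatives and the rule for named genes were fixed before the data were examined. The lists covered the NEDD8 pathway and COP9 signalosome, cullins and cullin adaptors, targets of NRF2, HIF, NF-kappaB, Wnt beta-catenin, p53, JAK-STAT feedback and Hedgehog, G1/S and DNA replication, G2/M and mitosis, CDK inhibitors and cyclins, interferon-stimulated genes, ATF4 and the unfolded protein response, cholesterol biosynthesis, TGF-beta with myofibroblast and matrix genes, immediate early and SRF targets, the circadian clock, the proteasome, apoptosis regulators, ribosomal proteins, and markers of macrophages, epithelium, endothelium, adipocytes and skeletal muscle. They held 774 genes, of which 703 had a probe set, and the 22 lists with at least 5 tested members were tested. The rule named, per comparison, both targets, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap (leaving out clone-type names), the 4 tested members with the smallest p of each list, the genes past the threshold in both knockdowns with the largest changes (4 per direction, and 4 of opposite direction), and NEDD8 pathway and cullin members past the threshold in any comparison. Of these 127, 127 and 122 genes, the text prints mainly the largest changes, examples of the lists called shifted and of the NEDD8 and cullin lists, and shared or opposite genes. The choice among them was made after their values were seen, and favoured calls that held when single arrays were left out.

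The overlap of the knockdowns was compared with 100 simulated data sets in which both targeted groups were unchanged and the controls shared. The alternatives tried were other constants (1 and 64), no filter and a stricter one, quantile normalization, median centring, eBayes without trend or robust, other choices among probe sets, a replicate block, only the 2 groups compared, other thresholds, and each array left out in turn. After the arrays had been inspected, 4 more were added, namely replicate 3 as a batch term, replicates 1 and 2 only, and as covariates the signal of the hybridization spikes or the 3' to 5' ratio of beta-actin. The steps were tested on simulated data with the same groups and 10613 genes. With a true log2 change of 0.5, 1 or 2 they recovered 17.9, 76.1 and 98.5% of changed genes for Ube2m shRNA against control, 43.3, 83.6 and 100% for Ube2f shRNA against control and 23.9, 79.1 and 100% between the knockdowns. Each rate rests on 66 or 67 changed genes of a single draw, so its differences between comparisons may come from the genes drawn. Of the calls 3.03, 4.43 and 6.9% were false, camera found a list shifted by 0.4, and it called 0 of 21 unshifted lists. The simulated genes varied independently, without correlation inside lists and without a shift of replicate 3. These rates therefore do not show how the tests behave with correlated genes. The shifted list was the proteasome, whose estimated correlation in the real data was 0.6. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.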

Results

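The data were 9 expression arrays of RNA from NIH 3T3 cells, an established line of mouse embryonic fibroblasts. The cells carried a retroviral vector for a control short hairpin RNA (shRNA), a hairpin against Ube2m or a hairpin against Ube2f, and RNA was taken 5 days after transduction. Each of the 3 groups held 3 biological replicates, per the labels. Ube2m and Ube2f encode the E2 enzymes that pass NEDD8, a ubiquitin-like protein, to cullins, the scaffolds of a large family of ubiquitin ligases. Going by its title, the series asks how separate pairs of E2 enzymes and RING proteins direct NEDD8 to particular cullins. The comparisons below ask which transcripts differed when either E2 was targeted, and which differed between the 2 targeted groups. The number of arrays limits the precision of every value. The median signal of all probe sets was 53.3 to 58.5 on replicates 1 and 2 of every group and 64, 73.2 and 73.5 on replicate 3 of the control, Ube2m and Ube2f groups. Values within replicates 1 and 2 and with replicate 3 set apart are therefore given beside the pooled ones for gene counts, for lists that camera called and for some other lists. The signal of the hybridization spikes in replicates 1 and 2 was 3069 and 2718 in control, against 4014 to 4625 with the targeting hairpins. In replicate 3 the order was reversed, with 3846 in control, 2687 with Ube2m and 2712 with Ube2f shRNA. Comparisons with control inside replicates 1 and 2 alone are therefore confounded with the spike level. Control replicate 1 had a ratio of 3' to 5' beta-actin signal of 1.82, against 1.24 to 1.35 on the other 8 arrays.

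Ube2f RNA was strongly reduced by its own hairpin. Its signal was 132 ± 13.2 in the Ube2f shRNA group and 2540 ± 199 in the control group (SD, n = 3 arrays each), or 5.21% of control. The log2 fold change was -4.11 (SE 0.12, adjusted p = 7.45e-10), and the 3 arrays read 134.9, 117.9 and 143.8 against 2367, 2492 and 2757. Of 6 probe sets for Ube2f, 1 did not follow, with 103 ± 40.4 against 89.3 ± 40.4 in control. The mean over all 6 probe sets gave a smaller log2 fold change of -2.71. In the Ube2m shRNA group the Ube2f signal was 2960 ± 229, a log2 difference of 0.22 from control that did not pass (SE 0.12, adjusted p = 0.278). This difference was 0.05 with probe sets averaged and 0.08 without probe sets that may match several transcripts. In replicates 1 and 2 alone it was 0.34 (limma adjusted p = 0.0684). No probe set assigned to 1 gene carried the name Ube2m in the probe table used, and those assigned to several genes were left out. The reduction of Ube2m was therefore not checked here. The growth label of all 9 samples describes the cells as expressing Ube2f. Whether this means an added Ube2f construct is not given in the sources used here, so the source of the Ube2f signal in each group is open.

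**Figure D1:**
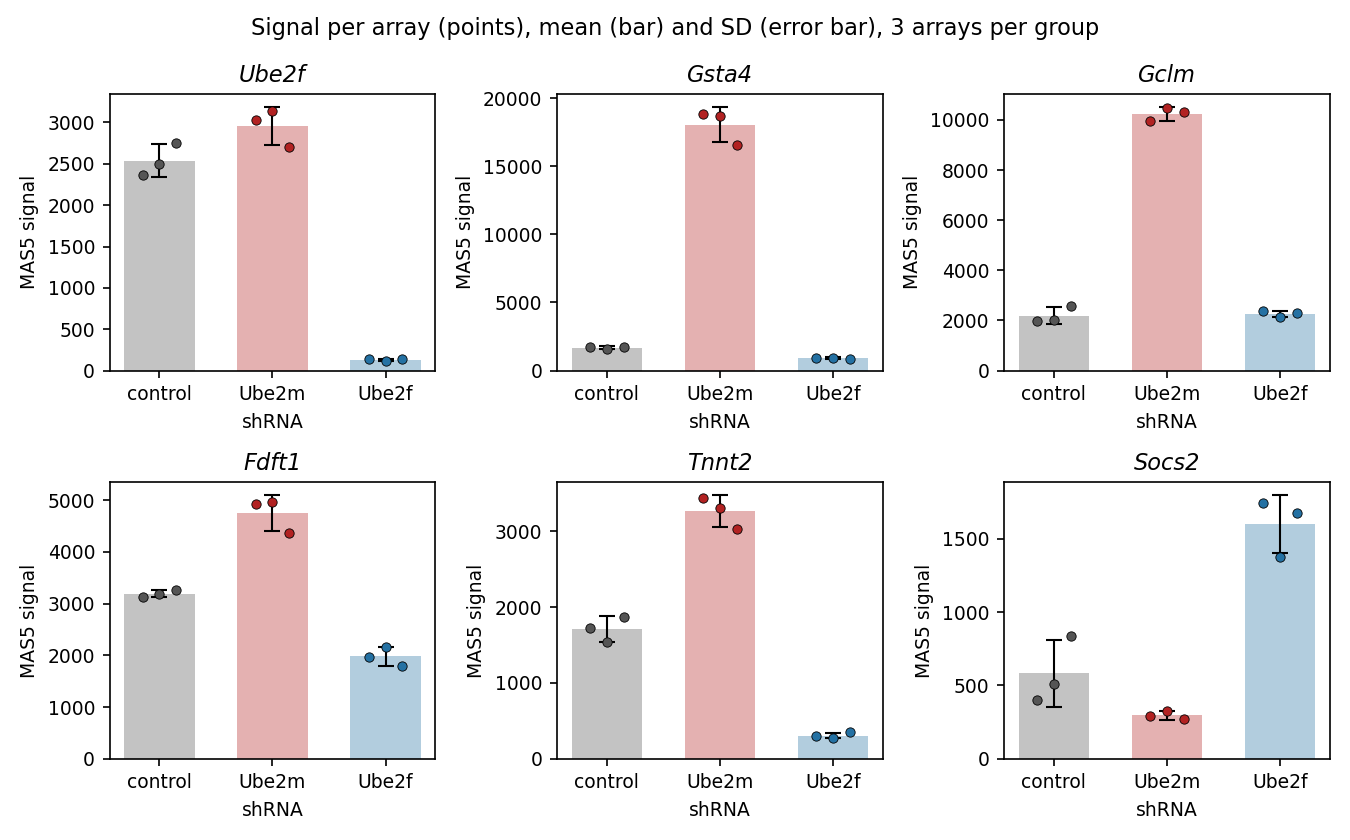
Signal per array (MAS5 intensity, vertical axis) of Ube2f, Gsta4, Gclm, Fdft1, Tnnt2 and Socs2 in the control, Ube2m and Ube2f shRNA groups, with 1 point per array, a bar at the mean and error bars of 1 SD (n = 3). Ube2f lies at 117.9 to 143.8 on the Ube2f shRNA arrays and at 2367 or higher on all others, while Gsta4 has a mean of 18000 in the Ube2m shRNA group and 1670 in control.

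With Ube2m shRNA, genes for detoxifying and glutathione enzymes were among the largest rises over control. Gsta4, a glutathione S-transferase, rose from 1670 ± 107 to 18000 ± 1290 (SD, n = 3 arrays each), a log2 fold change of 3.42 (SE 0.1, adjusted p = 1.72e-09). Its relatives Gsta3 and Gsta2 rose by log2 values of 4.68 (SE 0.33, adjusted p = 5e-06) and 4.53 (SE 0.41, adjusted p = 4.3e-05), although transcripts of this family may share probes. Aldh3a1, an aldehyde dehydrogenase, rose by 3.94 (adjusted p = 4.47e-06), and the transporter gene Abcc4 rose from 744 ± 37.8 to 4800 ± 525 (log2 fold change 2.66, adjusted p = 1.98e-07). Calr3 (3.31, adjusted p = 0.000398), the interferon-inducible GTPase gene Igtp (2.8, adjusted p = 0.00106) and Fyb (2.38, adjusted p = 0.00947) completed the 8 largest rises. Control signals of Gsta3, Gsta2, Aldh3a1, Calr3, Igtp and Fyb were at or under the low-signal level of 53.8, so their folds depend on the constant added before the logarithm. With 64 in place of 16 their log2 fold changes were 3.39, 3.28, 3.19, 2.73, 1.77 and 1.72, so their places among the largest rises may depend on it too. The largest fall was that of Car6, a secreted carbonic anhydrase gene, from 838 ± 191 to 112 ± 11.3 (log2 fold change -2.72, SE 0.24, adjusted p = 4.04e-05). Genes of matrix proteins followed, with elastin (Eln, -2.19, adjusted p = 0.000862), Prelp (-2.04, adjusted p = 0.000412) and Ltbp2 (-1.92, adjusted p = 0.000195). The small GTPase gene Rhob fell by 1.83 on the log2 scale (adjusted p = 4.47e-06) and Atf5, a stress-response transcription factor gene, by a log2 fold change of -1.8 (adjusted p = 0.000229). The other 2 of the 8 largest falls, Raly (-1.88, adjusted p = 0.0167) and Rab5c (-1.81, adjusted p = 0.0249), did not pass when any of several arrays was left out, mostly at similar folds. Without control replicate 1 Raly had -1.72 (adjusted p = 0.0866) and Rab5c -1.64 (adjusted p = 0.115). Without Ube2m replicate 1 they had -1.75 (adjusted p = 0.0657) and -1.63 (adjusted p = 0.0945). Without Ube2m replicate 2 they had -1.88 (adjusted p = 0.0583) and -1.79 (adjusted p = 0.0809). Rab5c also did not pass without control replicate 3 (-1.36, adjusted p = 0.0633). Over all arrays left out in turn the folds were -2.52 to -1.4 for Raly and -2.44 to -1.36 for Rab5c. With all its probe sets averaged Raly had -0.71 (adjusted p = 0.204).

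In all, limma with Benjamini-Hochberg adjustment called 1031 of 10613 genes changed between Ube2m shRNA and control (9.71%), 381 higher and 650 lower, of which 593 differed by at least 1.5-fold, 239 higher and 354 lower. With each array centred on its median the split was 534 higher and 432 lower, so the excess of falls depended on the scaling. In 1028 of the 1031 the 3 arrays of one group all lay above the 3 of the other. This held for 3151 of all genes tested (29.7%), where chance gives 10%. With replicate 3 as a batch term 2118 genes passed, 827 higher and 1291 lower. Replicates 1 and 2 alone gave 1747 genes, 682 higher and 1065 lower, of which 87.7% had the same direction in replicate 3, against 65.2% of all genes, and 927 were among the 1031. The count fell to 472 without control replicate 1, 443 without Ube2m replicate 1 and 388 without Ube2m replicate 2. It was 607 with all probe sets of a gene averaged and 448 with the beta-actin ratio as a covariate.

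Among the gene lists fixed before the data were examined, targets of NRF2, the transcription factor of the antioxidant response, were the most shifted by Ube2m shRNA. Of 27 tested members 22 rose and 0 fell (24 higher and 1 lower when adjusted over the list alone), with a median log2 fold change of 1.05 (camera adjusted p = 9.75e-33, and adjusted p = 0.0065 with an estimated correlation). They included Gclm, a subunit of the enzyme limiting glutathione synthesis, from 2200 ± 338 to 10200 ± 269 (log2 fold change 2.22, SE 0.11, adjusted p = 3.24e-07), and Blvrb, a biliverdin reductase gene (1.64, SE 0.11, adjusted p = 3.49e-06). The list median was 1.1 in replicates 1 and 2 and 0.92 in replicate 3. Of 49 genes of G2/M and mitosis 3 passed, all higher, namely Cdca2 (0.67, adjusted p = 0.0361), Kif20a (0.53, adjusted p = 0.0378) and Kif2c (0.52, adjusted p = 0.0409). Adjusted over the list alone 0 passed by limma, beside 20 higher and 0 lower at an unadjusted p under 0.05. The list median was 0.23, with 0.27 in replicates 1 and 2 and 0.23 in replicate 3 (camera adjusted p = 2.88e-07, and adjusted p = 0.0065 with an estimated correlation). Of 35 interferon-stimulated genes 5 rose and 0 fell (8 higher and 2 lower adjusted over the list alone), with a median of 0.25 (camera adjusted p = 3.68e-04, and adjusted p = 0.028 with an estimated correlation). Besides Igtp these were the viral RNA sensor gene Ddx58, from 389 ± 32.9 to 627 ± 23.7 (log2 fold change 0.67, adjusted p = 0.00659), Oas1a (1.56, adjusted p = 0.0105), whose transcripts may share probes with related Oas genes, Ifit1 (1.2, adjusted p = 0.0155) and Trim25 (0.42, adjusted p = 0.0251), the last named after its value was seen. Control signals of Oas1a and Ifit1 were under 53.8, and with a constant of 64 their log2 fold changes were 0.93 and 0.75. The interferon median was 0.2 in replicates 1 and 2 and 0.26 in replicate 3.

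Of 26 cholesterol biosynthesis genes 8 rose and 0 fell with Ube2m shRNA (10 higher and 0 lower adjusted over the list alone), among them Fdft1, which encodes squalene synthase, from 3200 ± 72.3 to 4750 ± 341 (log2 fold change 0.57, SE 0.1, adjusted p = 0.00536), and Fdps (0.6, SE 0.13, adjusted p = 0.0124). The median was 0.23, with 0.2 in replicates 1 and 2 and 0.28 in replicate 3 (camera adjusted p = 1.44e-05, but adjusted p = 0.35 with an estimated correlation and 0.0795 by fry). Proteasome subunits had a median of 0.18 over 37 members, with 0.18 in replicates 1 and 2 and 0.04 in replicate 3 (camera adjusted p = 1.65e-04, but adjusted p = 0.71 with an estimated correlation). By limma 0 of them passed, also when adjusted over the list alone, with 10 higher and 0 lower at an unadjusted p under 0.05, and fry gave an adjusted p of 0.386. The proteasome median was 0.09 without control replicate 3. Of 45 genes of TGF-beta response, myofibroblasts and matrix 3 rose and 11 fell (5 higher and 13 lower adjusted over the list alone). The proteoglycan gene Dcn fell from 658 ± 77.6 to 184 ± 29.9 (log2 fold change -1.75, SE 0.18, adjusted p = 0.000132, and -0.99 with its probe sets averaged), and its relative Bgn from 14300 ± 615 to 9210 ± 407 (-0.63, SE 0.093, adjusted p = 0.00138). Those that rose were the smooth muscle gene Cnn1 (0.78, SE 0.11, adjusted p = 0.00134), Tgfb2 (0.88, adjusted p = 0.0171) and Thbs1 (0.41, adjusted p = 0.0406), the last 2 named after their values were seen. This list's median was -0.20 (camera adjusted p = 0.0155, but adjusted p = 0.68 with an estimated correlation and 0.0795 by fry), with -0.14 in replicates 1 and 2 and -0.35 in replicate 3. The shift was not called without control replicate 3 (median -0.10, adjusted p = 0.36) or in replicates 1 and 2 alone (adjusted p = 0.18).

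Several of these single-gene calls for Ube2m shRNA against control lay near the threshold and were lost when 1 array was left out, for most of them any of several. Those of Igtp, Ddx58, Fdft1, Dcn, Bgn, Cnn1, Gclm and Blvrb passed without any 1 of the 9 arrays. With each array left out in turn the log2 fold change was 0.47 to 0.8 for Cdca2, 0.45 to 0.68 for Kif20a, 0.41 to 0.64 for Kif2c and 0.47 to 0.71 for Fdps. It was 1.26 to 1.77 for Oas1a, 1.13 to 1.3 for Ifit1, 0.35 to 0.48 for Trim25, 0.77 to 0.98 for Tgfb2 and 0.34 to 0.49 for Thbs1. Without Ube2m replicate 1 the adjusted p was 0.0961 for Cdca2, 0.15 for Kif20a, 0.138 for Kif2c, 0.0635 for Ifit1, 0.0799 for Trim25, 0.0641 for Tgfb2 and 0.0894 for Thbs1. Without Ube2m replicate 2 it was 0.0752 for Cdca2, 0.157 for Kif20a, 0.127 for Kif2c, 0.063 for Fdps, 0.0607 for Oas1a, 0.0973 for Trim25, 0.0781 for Tgfb2 and 0.103 for Thbs1. Without Ube2m replicate 3 it was 0.0981 for Cdca2, 0.0567 for Kif2c, 0.0632 for Trim25 and 0.12 for Thbs1. Without control replicate 1 it was 0.132 for Cdca2, 0.124 for Kif20a, 0.118 for Kif2c, 0.0526 for Fdps, 0.0556 for Trim25, 0.0509 for Tgfb2 and 0.106 for Thbs1. Without control replicate 2 it was 0.0562 for Cdca2, 0.0832 for Trim25, 0.0573 for Tgfb2 and 0.13 for Thbs1. Without control replicate 3 it was 0.0827 for Kif20a and 0.108 for Kif2c. Without Ube2f replicate 1 it was 0.0529 for Kif20a and 0.0661 for Thbs1. Without Ube2f replicate 2 it was 0.0554 for Kif2c. With all probe sets of a gene averaged, Cdca2 (0.43, adjusted p = 0.0777), Kif20a (0.53, adjusted p = 0.053), Kif2c (0.51, adjusted p = 0.0882), Fdft1 (0.47, adjusted p = 0.0816), Fdps (0.43, adjusted p = 0.264) and Ddx58 (0.52, adjusted p = 0.129) did not pass.

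**Figure D2:**
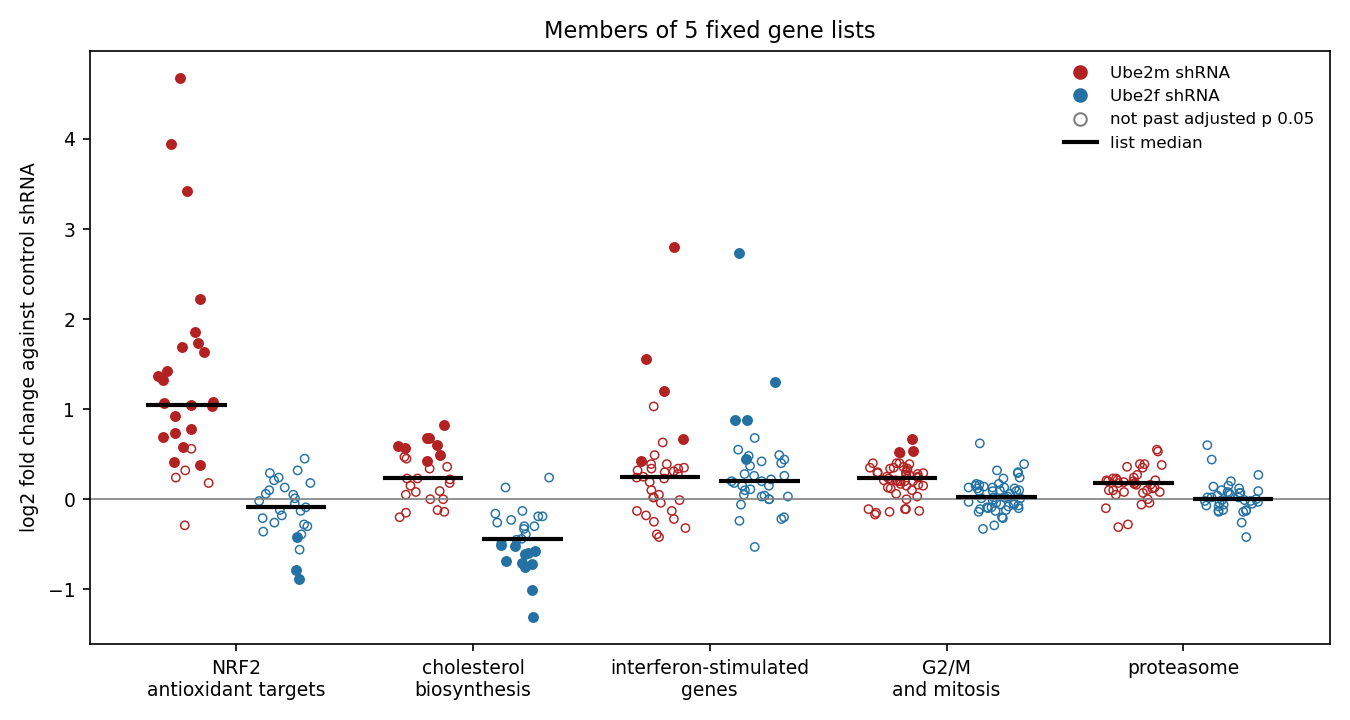
Log2 fold change against control shRNA (vertical axis) of the tested members of 5 gene lists, with 1 point per gene for Ube2m shRNA (red) and Ube2f shRNA (blue), filled where the adjusted p was under 0.05, and a bar at each median. The NRF2 median is 1.05 with Ube2m shRNA and -0.09 with Ube2f shRNA, and the cholesterol medians are 0.23 and -0.44.

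With Ube2f shRNA, the largest fall besides that of Ube2f itself was that of Flna, which encodes the actin cross-linker filamin A, from 7030 ± 976 to 1100 ± 263 (SD, n = 3 arrays each; log2 fold change -2.68, SE 0.17, adjusted p = 2.86e-06). Tnnt2, the cardiac troponin T gene, fell from 1710 ± 168 to 306 ± 37.8 (-2.42, SE 0.12, adjusted p = 4.03e-07), and the muscle gene Mustn1 from 1510 ± 105 to 397 ± 66.1 (-1.89, SE 0.15, adjusted p = 3.12e-05). Mgp (-1.86, adjusted p = 0.00035), Npr3 (-1.81, adjusted p = 0.00225), Erlin1 (-1.77, adjusted p = 2.86e-06) and Sox21 (-1.71, adjusted p = 0.00262) followed. Among the rises, Igtp went from 22.6 ± 24.3 to 210 ± 10.5 (2.73, SE 0.4, adjusted p = 0.00191) and the calpain gene Capn6 from 77 ± 18.2 to 543 ± 11.1 (2.6, SE 0.26, adjusted p = 0.000157). Tgfbi, a matrix gene induced by TGF-beta, rose from 643 ± 77.9 to 2390 ± 314 (1.87, SE 0.15, adjusted p = 3.12e-05), and the chemokine gene Ccl7 from 989 ± 120 to 3510 ± 590 (1.8, SE 0.16, adjusted p = 6.82e-05). Islr (2.09, adjusted p = 0.00202), C1ra (1.51, adjusted p = 0.0102), Rnpep (1.5, adjusted p = 6.82e-05) and Gpatch11 (1.67, adjusted p = 0.0184, and 0.0728 without Ube2f replicate 1) were the rest of the 8 largest rises. Signals of Igtp, Islr and Gpatch11 in control and of Npr3 with Ube2f shRNA were at or under 53.8, and with a constant of 64 their log2 fold changes were 1.69, 1.53, 1.13 and -1.23. Their places among the largest changes may therefore depend on the constant. With all probe sets of a gene averaged, Tnnt2 had -1.42, Erlin1 -0.97 and Npr3 -1.05, all past the threshold.

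Between Ube2f shRNA and control limma called 551 of 10613 genes changed (5.19%), 237 higher and 314 lower, with 367 at 1.5-fold or more, 150 higher and 217 lower. In all 551 the arrays of the 2 groups did not overlap, as in 2462 of all genes tested (23.2%, where chance gives 10%). With replicate 3 as a batch term 1461 genes passed, 721 higher and 740 lower. Replicates 1 and 2 alone gave 1121, 523 higher and 598 lower, of which 88.7% had the same direction in replicate 3, against 63% of all genes, and 495 were among the 551. The count fell to 281 without control replicate 1, 195 without Ube2f replicate 1 and 342 without Ube2f replicate 2. It was 271 with all probe sets of a gene averaged, 350 with only the 2 groups compared and 249 with the beta-actin ratio as a covariate.

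Of 26 cholesterol biosynthesis genes 0 rose and 11 fell with Ube2f shRNA (0 and 14 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 7.37e-11, but adjusted p = 0.19 with an estimated correlation, and adjusted p = 0.00642 by fry). Mvd, of the mevalonate pathway, fell from 706 ± 83.9 to 342 ± 10.2 (log2 fold change -1.01, SE 0.13, adjusted p = 0.00111), Sqle, which encodes squalene epoxidase, from 4460 ± 526 to 2650 ± 392 (-0.75, SE 0.13, adjusted p = 0.00578), and Fdft1 from 3200 ± 72.3 to 1980 ± 182 (-0.69, SE 0.1, adjusted p = 0.00225). With all probe sets of a gene averaged, Fdft1 no longer passed (-0.3, adjusted p = 0.33). The list's median was -0.49 in replicates 1 and 2 and -0.4 in replicate 3. Of 35 interferon-stimulated genes 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.20, or 0.12 in replicates 1 and 2 and 0.33 in replicate 3 (camera adjusted p = 1.35e-03, but adjusted p = 0.096 with an estimated correlation, where the unadjusted p was 0.0044, and adjusted p = 0.00124 by fry). They were Igtp, the guanylate-binding protein gene Gbp2, from 135 ± 2.67 to 262 ± 23.4 (0.88, adjusted p = 0.00997), the immunoproteasome gene Psmb9 (0.88, adjusted p = 0.0287), Trim25 (0.45, adjusted p = 0.0278) and Oas1a (1.3, adjusted p = 0.036). With a constant of 64 Oas1a had 0.73 and did not pass (adjusted p = 0.0598). With each array left out in turn the log2 fold changes were 0.84 to 0.95 for Gbp2, 0.79 to 0.98 for Psmb9, 0.38 to 0.5 for Trim25 and 1.16 to 1.47 for Oas1a, so these calls lay near the threshold. Without Ube2f replicate 1 the adjusted p was 0.0586 for Gbp2, 0.153 for Psmb9, 0.0906 for Trim25 and 0.119 for Oas1a. Without Ube2f replicate 2 it was 0.0869 for Psmb9, 0.0725 for Trim25 and 0.0656 for Oas1a. Without Ube2f replicate 3 it was 0.0633 for Trim25 and 0.0872 for Oas1a. Without control replicates 1, 2 or 3 it was 0.0541, 0.0978 and 0.0729 for Oas1a. Trim25 had 0.0597 without control replicate 1 and 0.0909 without control replicate 2. Psmb9 had 0.0712 without control replicate 2 and 0.073 without control replicate 3. Without Ube2m replicate 1 it was 0.0525 for Trim25 and 0.0538 for Oas1a, and without Ube2m replicate 2 it was 0.0566 for Trim25. NRF2 targets were not called shifted by Ube2f shRNA (median -0.09, with -0.03 in replicates 1 and 2 and -0.24 in replicate 3, camera adjusted p = 0.204), with 0 higher and 3 lower of 27, as also when adjusted over the list alone, and Gsta4 fell from 1670 ± 107 to 894 ± 70 (-0.89, SE 0.1, adjusted p = 0.000477). The 5 tested skeletal muscle genes, of 13 with a probe set, were called lower by camera (median -0.33, mean -0.68, camera adjusted p = 0.0299, but adjusted p = 0.19 with an estimated correlation, and adjusted p = 0.00124 by fry), although 1 of them passed, Tnnt2, with 0 higher and 1 lower adjusted over the list alone too. That call was lost without control replicate 3 (adjusted p = 0.087) and without Ube2f replicate 3 (median -0.18, adjusted p = 0.05), and without a filter on low signal (median -0.21, adjusted p = 0.092). Without Ube2f replicate 2 the median was -0.5, and it was -0.08 in replicates 1 and 2 and -0.7 in replicate 3.

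Directly compared, the 2 targeted groups differed in Ube2f itself (4.33, adjusted p = 1.96e-10) and in the same detoxification genes. Gsta4 had a signal of 18000 ± 1290 with Ube2m shRNA and 894 ± 70 with Ube2f shRNA (SD, n = 3 arrays each), a log2 difference of 4.31 (SE 0.1, adjusted p = 9.63e-11). Gsta3 was higher by 5.24 (SE 0.33, adjusted p = 1.56e-06) and Gsta2 by 4.78 (SE 0.41, adjusted p = 1.12e-05), or 3.61 and 3.38 with a constant of 64, as their signals with Ube2f shRNA were under 53.8. Tnnt2 was higher with Ube2m shRNA, at 3260 ± 211 against 306 ± 37.8 (3.35, SE 0.12, adjusted p = 5.02e-09), as was Cyp1b1, a cytochrome P450 gene, at 2230 ± 424 against 266 ± 70.3 (3.01, SE 0.22, adjusted p = 4.04e-06). Lower with Ube2m shRNA were Car6, at 112 ± 11.3 against 1690 ± 575 (-3.67, SE 0.24, adjusted p = 2.07e-06), Ccl7 (-2.61, SE 0.16, adjusted p = 1.56e-06), Dcn (-2.44, SE 0.18, adjusted p = 4.04e-06) and Capn6 (-2.44, SE 0.26, adjusted p = 6.16e-05). The same held for Socs2, a feedback inhibitor of cytokine signalling and a cullin adaptor, at 296 ± 28.6 against 1600 ± 196 (-2.37, SE 0.21, adjusted p = 1.74e-05), and for the chemokine gene Cxcl12 (-2.14, adjusted p = 3.62e-06). With all probe sets of a gene averaged, Ube2f had 2.76, Cyp1b1 1.92, Socs2 -1.38 and Cxcl12 -1.12, all past the threshold.

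Between these groups limma called 1672 of 10613 genes (15.8%), 676 higher and 996 lower with Ube2m shRNA, with 1036 at 1.5-fold or more, 441 higher and 595 lower. With each array centred on its median the split was 856 higher and 745 lower. In 1664 of the 1672 the groups did not overlap, as in 3647 of all genes tested (34.4%, where chance gives 10%). With replicate 3 as a batch term 2714 genes passed, 1072 higher and 1642 lower. Replicates 1 and 2 alone gave 2032, 820 higher and 1212 lower, of which 97.4% had the same direction in replicate 3, against 76.5% of all genes, and 1488 were among the 1672. The count fell to 1063 without Ube2m replicate 1, 1017 without Ube2m replicate 2 and 1018 without Ube2f replicate 1. It was 1109 with all probe sets of a gene averaged.

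Of 27 NRF2 targets 22 were higher and 1 lower with Ube2m than with Ube2f shRNA, also when adjusted over the list alone, with a median of 1.20, 1.24 in replicates 1 and 2 and 1.16 in replicate 3 (camera adjusted p = 3.88e-27, and adjusted p = 0.014 with an estimated correlation). The one lower was Ugdh (-0.5), named after its value was seen. Of 26 cholesterol genes 17 were higher and 0 lower (19 and 0 adjusted over the list alone), with a median of 0.61, 0.67 in replicates 1 and 2 and 0.72 in replicate 3 (camera adjusted p = 1.06e-16, but adjusted p = 0.065 with an estimated correlation, and adjusted p = 0.000487 by fry). Fdft1 had 4750 ± 341 against 1980 ± 182 (1.26, SE 0.1, adjusted p = 7.63e-06, and 0.77 with its probe sets averaged) and Mvd 802 ± 92.4 against 342 ± 10.2 (1.19, SE 0.13, adjusted p = 9.09e-05). Of 49 G2/M genes 9 were higher and 0 lower (10 and 0 adjusted over the list alone), with a median of 0.14, 0.12 in replicates 1 and 2 and 0.18 in replicate 3 (camera adjusted p = 6.03e-05, and adjusted p = 0.021 with an estimated correlation). The mitotic kinase gene Plk1 had 2500 ± 68.1 against 1790 ± 111 (0.48, SE 0.11, adjusted p = 0.00893). Of 37 proteasome genes 1 was higher and 0 lower, also adjusted over the list alone, namely Psmd11 (0.61, SE 0.11, adjusted p = 0.00301). The proteasome median was 0.16 in all replicates, 0.16 in replicates 1 and 2 and 0.18 in replicate 3 (camera adjusted p = 0.00239, but adjusted p = 0.77 with an estimated correlation and 0.386 by fry). That shift was lost without Ube2m replicate 1 (adjusted p = 0.057) and without Ube2f replicate 3 (median 0.07, adjusted p = 0.4), and the median was 0.25 without Ube2m replicate 3.

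Camera called 3 more lists between the knockdowns, ATF4 and unfolded protein response genes and Hedgehog targets as lower and muscle genes as higher with Ube2m shRNA. All 3 calls were lost with an estimated correlation (camera adjusted p = 0.67, 0.59 and 0.091), while fry gave adjusted p = 0.101, 0.0223 and 0.000487. Of 42 ATF4 and unfolded protein response genes 0 were higher and 8 lower (0 and 9 adjusted over the list alone), among them the chaperone gene Dnajb9, at 837 ± 102 against 1360 ± 64.6 (-0.7, SE 0.11, adjusted p = 0.00137), Aldh18a1, of proline synthesis (-0.57, SE 0.11, adjusted p = 0.00528), and Atf5 (-0.95, SE 0.2, adjusted p = 0.00719). The median was -0.24, also -0.24 in replicates 1 and 2 and -0.24 in replicate 3 (camera adjusted p = 0.00367, but adjusted p = 0.67 with an estimated correlation). This call was lost without Ube2f replicate 2 (adjusted p = 0.053) and without Ube2m replicate 3 (adjusted p = 0.058). Of 10 Hedgehog targets 0 were higher and 3 lower (0 and 4 adjusted over the list alone), namely Ccnd2 (-0.48, adjusted p = 0.0086), the receptor gene Ptch1 (-0.63, adjusted p = 0.00695), which read 0.02 (adjusted p = 0.979) as the mean of its probe sets, and the transcription factor gene Gli2 (-0.86, adjusted p = 0.0161). Gli2 did not pass without Ube2m replicate 1 (adjusted p = 0.0629), Ube2m replicate 2 (adjusted p = 0.071) or Ube2f replicate 1 (adjusted p = 0.0553). The Hedgehog median was -0.39, with -0.42 in replicates 1 and 2 and -0.28 in replicate 3 (camera adjusted p = 0.0206, but adjusted p = 0.59 with an estimated correlation), and the call was lost without Ube2m replicate 1 (adjusted p = 0.058) and without Ube2f replicate 3 (adjusted p = 0.13). Without a filter on low signal the Hedgehog median was -0.24 (adjusted p = 0.095). Of the 5 skeletal muscle genes 2 were higher and 0 lower, also adjusted over the list alone, Tnnt2 and the actin gene Acta1 (0.97, SE 0.17, adjusted p = 0.00253). The muscle median was 0.38, with -0.01 in replicates 1 and 2 and 0.97 in replicate 3 (camera adjusted p = 0.00457, but adjusted p = 0.091 with an estimated correlation). It was 0.65 without Ube2m replicate 1, 0.24 without Ube2m replicate 3, 0.6 without Ube2f replicate 1 and 0.22 with a constant of 64. Without a filter on low signal the muscle call was lost (median 0.16, adjusted p = 0.084).

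By camera the NEDD8 pathway and cullin lists were not called shifted in any comparison. By fry the NEDD8 list, which holds Ube2f itself, was called lower with Ube2f shRNA than in control (adjusted p = 0.00284) and higher with Ube2m than with Ube2f shRNA (adjusted p = 0.00332). Fry called the cullin list lower with Ube2m than with Ube2f shRNA (adjusted p = 0.0166). Of 23 tested genes of the NEDD8 pathway and the COP9 signalosome, the complex that removes NEDD8 from cullins, 0 rose and 3 fell with Ube2m shRNA, also when adjusted over the list alone (camera adjusted p = 0.961). With Ube2f shRNA 0 rose and 2 fell, Ube2f among them (1 and 3 adjusted over the list alone, camera adjusted p = 0.225), and between the 2 knockdowns 1 was higher, Ube2f, and 0 lower (adjusted p = 0.451 by camera). Cops7a, a COP9 signalosome subunit gene, fell with both hairpins, from 2760 ± 157 in control to 1740 ± 69.9 with Ube2m shRNA (-0.66, SE 0.1, adjusted p = 0.00188) and 1710 ± 129 with Ube2f shRNA (-0.68, SE 0.1, adjusted p = 0.00218), the latter not with its probe sets averaged (-0.42, adjusted p = 0.0647). Rnf7, which encodes the RING protein that works with UBE2F, fell with Ube2m shRNA (-0.48, adjusted p = 0.0363), as did Dcun1d2, a NEDD8 ligase cofactor gene (-0.45, adjusted p = 0.0192). Both calls lay near the threshold and were lost when any of several arrays was left out. Over all arrays left out in turn the log2 fold changes were -0.48 to -0.42 for Dcun1d2 and -0.59 to -0.36 for Rnf7. With probe sets averaged Dcun1d2 had -0.29 (adjusted p = 0.224) and Rnf7 -0.41 (adjusted p = 0.0838). Dcun1d2 had an adjusted p of 0.0556 without control replicate 1, 0.0554 without control replicate 2, 0.0924 without Ube2m replicate 1 and 0.0679 without Ube2m replicate 2. Rnf7 had 0.0564, 0.114 and 0.0618 without control replicates 1, 2 and 3, 0.0983 without Ube2m replicate 1 and 0.11 without Ube2m replicate 3. In this list the median for Ube2m shRNA was 0, the mean -0.04, and the direction up by camera and down by fry.

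Of 37 cullins and cullin adaptors 2 rose and 5 fell with Ube2m shRNA (4 and 7 adjusted over the list alone), 5 rose and 3 fell with Ube2f shRNA (6 and 3), and 2 were higher and 6 lower between the knockdowns (2 and 6). The camera adjusted p values were 0.536, 0.63 and 0.487. Socs2 rose with Ube2f shRNA from 582 ± 228 to 1600 ± 196 (1.49, SE 0.21, adjusted p = 0.00183, and 0.98 with its probe sets averaged), and so did Cish, another gene of this family (0.78, SE 0.16, adjusted p = 0.0153, with 0.0505 without control replicate 1 and 0.0655 without Ube2f replicate 2). Socs3 rose too (0.71, adjusted p = 0.00254), but not with all its probe sets averaged (0.48, adjusted p = 0.119) or without probe sets that may match several transcripts (0.29, adjusted p = 0.484). Dtl, the substrate receptor gene of a cullin 4 ligase, fell with Ube2f shRNA (-0.88, SE 0.12, adjusted p = 0.00113), although the mean of its 6 probe sets lay higher by 0.4 (adjusted p = 0.531). With Ube2m shRNA the cullin 3 adaptor gene Spop rose from 3440 ± 105 to 4650 ± 66.6 (0.43, SE 0.087, adjusted p = 0.00967, and 0.0528 without Ube2m replicate 1). Skp2, an F-box gene of cullin 1 ligases, was lower with Ube2m than with Ube2f shRNA, at 1630 ± 78.9 against 2660 ± 107 (-0.7, SE 0.096, adjusted p = 0.000448).

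Set side by side, the 2 knockdowns shared some changes and opposed each other in others. Igtp rose with both hairpins, by log2 values of 2.8 and 2.73. The giant cytoskeletal protein gene Ahnak2 fell with both, from 2460 ± 399 in control to 1250 ± 144 with Ube2m shRNA (-0.96, adjusted p = 0.00292) and 1050 ± 205 with Ube2f shRNA (-1.23, adjusted p = 0.00105), as did Fam120c (-1.19, adjusted p = 0.00114, and -1.28, adjusted p = 0.00119) and Cdr2l (-1.17, adjusted p = 0.00142, and -1.11, adjusted p = 0.00307). With all probe sets averaged, Fam120c no longer passed for Ube2m shRNA (-0.52, adjusted p = 0.147) nor Cdr2l for Ube2f shRNA (-0.62, adjusted p = 0.0927), and Fam120c had -0.85 for Ube2f shRNA. Gsta4 rose with Ube2m shRNA and fell with Ube2f shRNA, as did Tnnt2 (0.93, SE 0.12, adjusted p = 0.000705 with Ube2m shRNA). In all 159 genes passed in both comparisons with control, 54 higher in both and 60 lower in both, where independent lists of these sizes would share 8.51 and 19.2. Another 27 were higher with Ube2m and lower with Ube2f shRNA (11.3 for independent lists) and 18 the reverse (14.5). All 45 also passed between the knockdowns, which was all but fixed in advance, since opposite differences from the same controls add up there. Both comparisons use the same 3 control arrays, so part of any sharing comes from the controls, and 3 arrays could not be split into separate control sets of 2. Over all 10613 genes, which are not independent replicates, the 2 log2 fold changes had a Pearson r of 0.25 and a covariance of 0.0295, and 60.6% had the same sign. Simulated unchanged groups with shared controls gave 0.5, 0.0187 and 66.7% (100 draws). The simulated arrays varied independently, so the shared deviation of replicate 3 is not in these values. They also held no real change, and a real change particular to 1 hairpin can lower both r and the share of equal signs. An r and a share under the simulated ones therefore do not show that the hairpins acted less alike than chance. The correlation was 0.36 without control replicate 2 and 0.35 without control replicate 3.

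**Figure D3:**
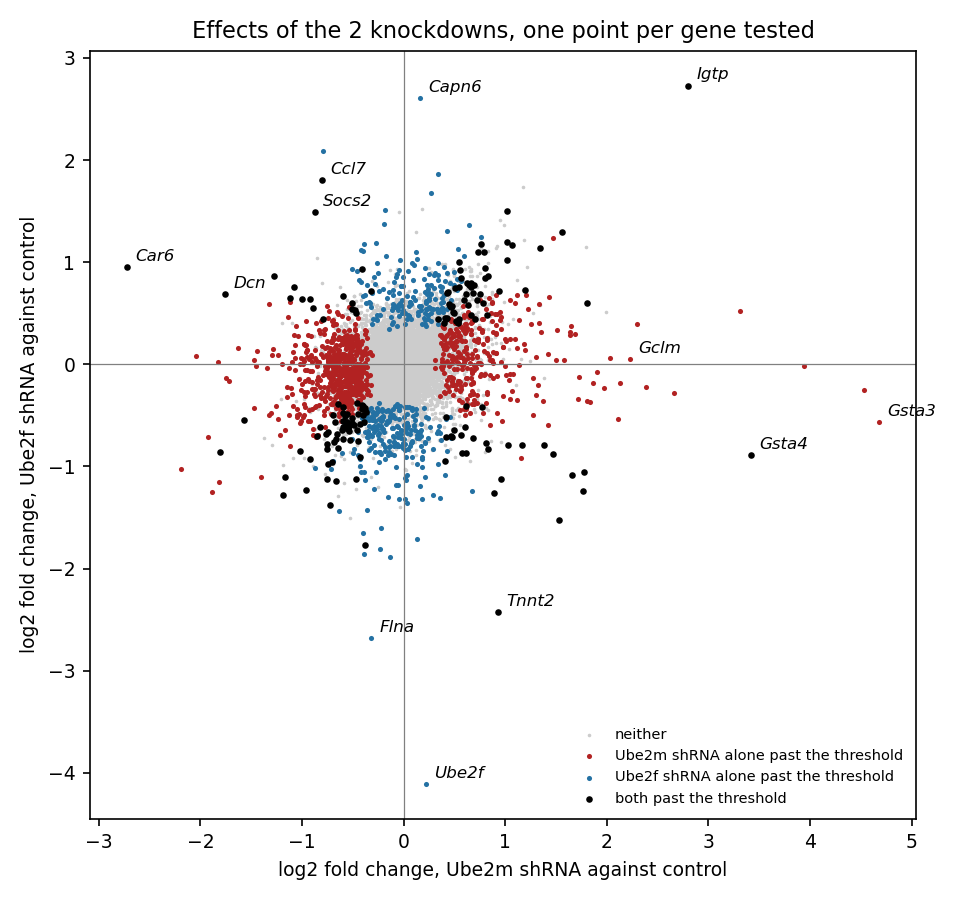
Log2 fold change with Ube2f shRNA (vertical axis) and with Ube2m shRNA (horizontal axis), each against control shRNA, with 1 point per gene tested (10613), coloured by the comparison in which it passed. The r over all genes is 0.25, beside 0.5 in simulated unchanged groups with shared controls. Igtp lies high on both axes, and Gsta4 and Tnnt2 lie in opposite directions.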

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

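Of the tests in this part, those chosen only after results were seen were the median over NRF2 targets outside the glutathione S-transferase family, the list medians under other groupings of the arrays, the fit with the spike level as a covariate, and the fits with the spike level and replicate 3 together. All bootstrap intervals given below resampled the genes of a list, not the arrays. They show the spread between co-regulated genes and not the variation between cultures, and some of the differences rest on a single array per group.

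Probe sets without a gene name were left out of the comparisons, and some of them stood above control. Of 2269 such probe sets with enough signal, 31 were higher than in control with Ube2m shRNA and 4 with Ube2f shRNA, while 21 and 22 were lower. In all 2.29% and 1.15% passed, against 4.45% and 2.89% of all probe sets, and between the knockdowns 102 passed (4.5%, against 9.53% of all probe sets).

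NRF2 targets were higher with Ube2m shRNA than in control, with 22 of 27 past the threshold and a median log2 fold change of 1.05. The tables argue against brightness of the arrays, read from the hybridization spikes, as the whole cause, since Ube2m replicate 3 and control replicates 1 and 2 shared a spike level and still differed by a median of 0.94 (95% bootstrap interval 0.58 to 1.24), which mixes in any shift of replicate 3, and as the median was 1.01 (0.68 to 1.41) with spike level and replicate 3 both in the fit. They also argue against the high beta-actin ratio of control replicate 1, as the median without that array was 0.98 (0.72 to 1.46), and against shared probes among glutathione S-transferases, as the 22 members outside that family had a median of 1.04 (0.69 to 1.35). A biological hypothesis is that NRF2 may be degraded less when Ube2m is targeted, since the ligase that degrades it is built on cullin 3, a NEDD8 target. It stays untested, as NRF2 protein was not measured, the reduction of Ube2m was not checked, and an off-target effect of the hairpin remains open. RNA of Nfe2l2, the gene of NRF2, did not pass by limma (log2 fold change -0.11, SE 0.09, adjusted p = 0.485).

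Cholesterol biosynthesis genes differed between the knockdowns, with 17 of 26 higher with Ube2m than with Ube2f shRNA and a median of 0.61. The list's camera call was lost with an estimated correlation (adjusted p = 0.065). Fry, which compares the list with no other genes, gave an adjusted p of 0.000487. Replicate 3 of both groups shared a spike level and differed by a median of 0.72 (95% bootstrap interval 0.39 to 0.89), and with spike level and replicate 3 both in the fit the median was 0.61 (0.41 to 1.04), which argues against array brightness as the whole cause. The smallest of the 6 medians with 1 array of either group left out was 0.59 (0.42 to 0.98), which argues against a single array. Co-regulation of these genes, which share the SREBP transcription factors, limits what the list test shows. The groups may differ in SREBP activity as a biological hypothesis, and neither sterol level nor culture density was measured, so both stay open.

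Of 35 interferon-stimulated genes 5 passed as higher than in control with each targeting hairpin, and the list's call was kept for Ube2m shRNA (adjusted p = 0.028 with an estimated correlation) but lost for Ube2f shRNA (adjusted p = 0.096 with an estimated correlation). Before adjustment over the lists these camera p values were 0.0039 and 0.0044, so the split comes from the adjustment and shows no difference between the hairpins. The list's estimated correlation was -0.0088, under the preset 0.01, so correlated genes do not account for the lost call. Fry gave adjusted p = 0.000686 and 0.00124. Replicate 3 of both targeted groups exceeded control replicates 1 and 2, which share a spike level with them, by a median of 0.26 (95% bootstrap interval 0.06 to 0.45), which mixes in any shift of replicate 3, whereas with spike level and replicate 3 both in the fit the median was 0.21 (0.07 to 0.38), which argues against brightness as the whole cause. The smallest of the 3 medians without 1 control array was 0.15 (0.1 to 0.41), which argues against 1 low control array, though it lies at the bound of 0.15 set for that test. A response to the double-stranded hairpin RNA may differ between vectors, and a biological effect of blocked NEDD8 transfer is the other hypothesis. These cannot be separated here, because each target was represented by 1 group of arrays and the number of hairpins per gene is not given in the sources used here.

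With 3 arrays against 3 there are 10 groupings of the arrays, too few for a share under 0.05. For genes the real grouping gave 1031, 551 and 1672 in the 3 comparisons and the highest other 0, 1 and 0, so that 1 grouping of 10, the real one, gave as many each time. Any real difference lies inside the groups of every other grouping and widens their spread, so low counts there do not measure chance. For lists the real grouping gave 6, 3 and 7 and the highest other 9, 7 and 8, and 7, 9 and 4 groupings gave as many. The grouping of control replicates 1 and 2 with Ube2m replicate 3, which follows the spike level, gave 9 lists, where the spike level as a covariate left 6 for Ube2m shRNA against control and the replicate block 6. The grouping of control replicates 1 and 2 with Ube2f replicate 3 gave 4 lists, where the covariate gave 5 for Ube2f shRNA against control and the block 4. For NRF2 the largest absolute median of any other grouping was 0.41 for Ube2m shRNA against control, beside the real 1.05. For cholesterol between the knockdowns it was 0.41 beside 0.61, and for interferon it was 0.11 beside 0.25 with Ube2m and 0.11 beside 0.20 with Ube2f shRNA. For 6 other list calls the real median did not exceed those of the other groupings, which reached 0.23 beside 0.23 for cholesterol and 0.23 beside 0.18 for the proteasome with Ube2m shRNA and 0.37 beside 0.33 for muscle with Ube2f shRNA. Between the knockdowns they reached 0.28 beside 0.24 for ATF4 and unfolded protein response, 0.29 beside 0.16 for the proteasome and 0.66 beside 0.38 for muscle. Each other grouping still sets 2 arrays of one group with 1 of the other against the rest, so it keeps part of any real difference, and a smaller median there shows little.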

How the results depend on the processing

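Tests added after results were seen were the batch term, replicates 1 and 2 alone, and the spike and beta-actin covariates. Over 120 printed gene results and 2967 values under alternatives, 2809 kept direction and side of the threshold, 155 kept direction but no longer passed, 0 newly passed and 3 turned. The choice of printed genes favoured calls that held when single arrays were left out, and those fits are among the alternatives. Most printed genes and all lists counted had passed as reported, so few or none could newly pass. The tally describes the printed results and not all genes tested. With the mean of all probe sets, Dtl read 0.40 (adjusted p = 0.531) for Ube2f shRNA against control, Flt1 0.08 (0.885) for Ube2m shRNA against control, and Ptch1 0.02 (0.979) between the knockdowns. Settings other than left-out arrays and averaged probe sets ended calls of Oas1a, Cdca2, Kif20a, Kif2c, Rnf7, Thbs1, Psmb9, Cd14, Gbp2, Rab5c, Raly, Trim25, Dcun1d2, Flt1, Fyb, Ifit1, Tgfb2, Cish, Socs3 and Gpatch11. For the 16 list shifts 274 of 304 values were kept, 30 no longer passed and 0 turned. Counts below are in the order Ube2m against control, Ube2f against control, Ube2m against Ube2f. The mean of all probe sets gave 607, 271 and 1109 genes, and at least 1.5-fold gave 593, 367 and 1036, fewer by construction. The replicate block gave 1866, 1225 and 2493, adjusted p under 0.10 gave 1622 and 960, more by construction, for the first 2, and only the 2 groups compared gave 350 for Ube2f. Replicate 3 as a batch term gave 2118, 1461 and 2714, replicates 1 and 2 alone 1747 and 1121, and the beta-actin covariate 448 and 249. Lists shifted numbered 3, 0 and 2 with an estimated correlation, and for Ube2f against control 6 in replicates 1 and 2 alone and 5 with the spike covariate. The correlation of the 2 knockdowns was 0.35 without a filter. Leaving out 1 array gave 388 to 1177, 195 to 583 and 1017 to 1813 genes, 3 to 5 lists for Ube2f against control, and correlations of 0.23 to 0.36. Ube2f in its knockdown read -4.25 to -2.71 over all alternatives, past the threshold in each. Except where stated, the cause was not tested. Leaving out an array leaves 2 in a group, whose spread the fit pools with the others. Whether replicate numbers pair the arrays is open. Deviations of the same number correlated by 0.2, 0.21 and 0.56 in replicates 1, 2 and 3 of Ube2m against Ube2f, all over 0.1, but by 0, 0.19 and 0.32 for Ube2m against control and 0.01, 0.16 and 0.35 for Ube2f against control. Replicate 3 thus deviated together in all groups, and 4 of 9 arrays correlated best with their own number. The alternatives for the Ube2m level were not run, as no probe set with a single gene carried its name. Folds against signals near 53.8 are limited by background.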

Other observations

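The 3 hypotheses that end this part were written after other results had been seen, and the members that prompted them were left out of their tests.

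Glucose transport, hypoxia and growth-control genes changed one by one, and camera called none of their lists shifted. Fry called the Wnt list higher with Ube2m than with Ube2f shRNA (adjusted p = 0.0119). Slc2a1, a glucose transporter gene among the HIF targets, rose with Ube2m shRNA from 3750 ± 100 to 8990 ± 1020 (SD, n = 3 arrays each; log2 fold change 1.25, SE 0.12, adjusted p = 9.8e-05), while Pdk1, also a HIF target, was lower with Ube2m than with Ube2f shRNA (-1.44, SE 0.14, adjusted p = 2.95e-05, and -0.79 with its probe sets averaged), as was Bnip3 (-0.93, SE 0.11, adjusted p = 0.000128). Of 28 HIF targets 2 rose and 3 fell with Ube2m shRNA, 3 rose and 1 fell with Ube2f shRNA, and 2 were higher and 5 lower between the knockdowns. Adjusted over the list alone these were 2 and 3, 5 and 1, and 2 and 6. Immediate early genes split likewise, as Klf4 fell with Ube2m shRNA from 8830 ± 302 to 4590 ± 672 (-0.95, SE 0.11, adjusted p = 0.000302), and Dusp4 (1.84, adjusted p = 0.00671) and Ier3 (1.35, adjusted p = 0.00662) rose. Of 33 members 2 rose and 1 fell with Ube2m shRNA, 3 and 0 with Ube2f shRNA, and 5 and 5 between the knockdowns (adjusted over the list alone 2 and 1, 5 and 1, 7 and 6). Against control the immediate early median changed sign between replicates. It was 0.26 in replicates 1 and 2 and -0.34 in replicate 3 with Ube2m shRNA, and 0.3 and -0.12 with Ube2f shRNA. Among 19 NF-kappaB targets 0 rose and 2 fell with Ube2m shRNA, 1 and 0 with Ube2f shRNA, and 1 and 3 between the knockdowns (adjusted over the list alone 1 and 2, 1 and 0, 1 and 3), the last including the chemokine gene Ccl2 (-1.17, SE 0.16, adjusted p = 0.000402) and Csf1 (-0.86, SE 0.18, adjusted p = 0.00576). Of 10 Wnt targets 1 and 1, 0 and 1, and 3 and 1 passed as higher and lower (adjusted over the list alone 1 and 1, 0 and 2, 3 and 1), with Lef1 higher with Ube2m than with Ube2f shRNA (1.26, SE 0.27, adjusted p = 0.00731), or 1.55 with a constant of 1 and 0.8 with 64. Of 17 JAK-STAT feedback targets 2 and 4, 4 and 1, and 2 and 5 passed (adjusted over the list alone 4 and 4, 4 and 3, 3 and 7), with the receptor gene Osmr lower with Ube2m shRNA (-0.9, SE 0.12, adjusted p = 0.000803), but not with its probe sets averaged (-0.54, adjusted p = 0.101).

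Cell cycle, p53 and apoptosis genes also went both ways, given here as counts higher and lower for Ube2m against control, Ube2f against control and Ube2m against Ube2f. Of 28 p53 targets 4 and 6, 0 and 1, and 3 and 1 passed (adjusted over the list alone 5 and 7, 0 and 2, 3 and 1), and Zmat3 fell with both hairpins (-0.76, SE 0.12, adjusted p = 0.00226, and -0.78, SE 0.12, adjusted p = 0.00263). Of 26 apoptosis regulators 6 and 2, 0 and 0, and 3 and 2 passed (adjusted over the list alone 6 and 3, 0 and 0, 3 and 3), and the death receptor gene Tnfrsf10b was higher with Ube2m than with Ube2f shRNA (0.81, SE 0.18, adjusted p = 0.00952). Of 17 CDK inhibitors and cyclins 1 and 4, 0 and 0, and 3 and 6 passed (adjusted over the list alone 1 and 4, 0 and 0, 3 and 7). Fry called this list lower with Ube2m shRNA than in control (adjusted p = 0.0445) and than with Ube2f shRNA (adjusted p = 0.0033), and Rbl2, a retinoblastoma-family gene, was lower with Ube2m than with Ube2f shRNA (-0.79, SE 0.15, adjusted p = 0.00349). Of 51 genes of G1/S and DNA replication 2 and 1, 0 and 0, and 3 and 1 passed (adjusted over the list alone 1 and 1, 0 and 0, 2 and 0). Of 37 ribosomal protein genes 1 and 0, 0 and 0, and 1 and 0 passed, also adjusted over the list alone, the last being Rps25 (0.86, SE 0.16, adjusted p = 0.00282). The ribosomal median was 0.22 in replicates 1 and 2 and -0.32 in replicate 3 with Ube2m shRNA, and 0.19 and -0.32 with Ube2f shRNA. Of 18 circadian clock genes 0 and 0, 0 and 0, and 0 and 1 passed (adjusted over the list alone 0 and 0, 0 and 1, 0 and 0). At an unadjusted p under 0.05 in limma, the counts of 0 stood beside 4 higher and 2 lower for apoptosis, 4 and 1 for CDK inhibitors and cyclins, 2 and 2 for G1/S and 1 and 0 for ribosomal proteins, all with Ube2f shRNA, and for the clock beside 1 and 4 with Ube2m and 1 and 3 with Ube2f shRNA. G2/M and proteasome genes had 0 past the threshold with Ube2f shRNA, beside 3 and 2, and 1 and 2, and Hedgehog targets 0 with Ube2m shRNA, beside 0 and 3. The Hedgehog median with Ube2m shRNA was -0.39 in replicates 1 and 2 and 0.04 in replicate 3. The response lists called in other comparisons had 1 and 4 of 42 for ATF4 and unfolded protein response with Ube2m shRNA (adjusted over the list alone 1 and 6) and 6 and 2 with Ube2f shRNA (9 and 3), where Xbp1 rose (0.71, SE 0.13, adjusted p = 0.00836). The camera adjusted p of all these lists was at least 0.0968.

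Signs of the list summaries differed in several lists that camera did not call. With Ube2m shRNA the median was -0.01 for HIF, -0.04 for Wnt and -0.02 for p53 targets, where camera pointed up, and the Wnt mean was 0.05. With Ube2f shRNA the median was -0.04 and the mean 0.08 for NF-kappaB targets, -0.03 and 0.10 for JAK-STAT targets, both up by camera, and 0.01 for G1/S, which was down. Between the knockdowns the median was -0.02 for interferon genes, -0.06 for apoptosis and -0.01 for G1/S, all up by camera, and 0.25 for NF-kappaB targets, where fry pointed down. Markers of other cell types had too few members above the low-signal level for a test, 4 of 14 for macrophages, 4 of 13 for epithelium, 2 of 11 for endothelium and 2 of 9 for adipocytes. Of these, the keratin gene Krt14 (0.98) and Cd14 (0.52) passed between the knockdowns. Cd14 did not pass without Ube2m replicate 1 (adjusted p = 0.121) or 2 (adjusted p = 0.0842), or without Ube2f replicate 1 (adjusted p = 0.05), 2 (adjusted p = 0.054) or 3 (adjusted p = 0.0935). Flt1, a receptor gene of endothelium, fell in both comparisons with control (-0.76 with Ube2m and -0.83 with Ube2f shRNA), but not without control replicate 1 (adjusted p = 0.106 and 0.1). With Ube2m shRNA it did not pass without Ube2m replicate 1 (adjusted p = 0.0812) or 2 (adjusted p = 0.082), and with Ube2f shRNA not without Ube2f replicate 1 (adjusted p = 0.111) or 2 (adjusted p = 0.0653). As the mean of its probe sets Flt1 read 0.08 with Ube2m shRNA (adjusted p = 0.885) and -0.4 with Ube2f shRNA (adjusted p = 0.357).

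As hypotheses, further members of 3 gene families might follow the few seen first, and none was settled. Imprinted genes had a median of -0.14 between the knockdowns (9 of 25 tested, 95% bootstrap interval -0.84 to 0.39, 2 higher and 1 lower). The lower one was Dlk1 (-0.84), and the higher ones were Slc38a4 (0.79) and Impact (0.39). Genes listed with the aryl hydrocarbon receptor, not all of them its targets, had a median of 0.23 with Ube2m shRNA (4 of 12 tested, -0.11 to 1.33, 1 higher, Xdh at 1.33). The others were Arnt (0.11), Nfe2l2 (-0.11) and Tiparp (0.34). Canonical histone genes had a median of -0.51 (4 of 21 tested, -0.92 to 0.23, 1 lower, H1f2 at -0.71, whose adjusted p was 0.0596 without control replicate 2, 0.0607 without Ube2m replicate 2 and 0.0609 without Ube2m replicate 3, and which read -0.38 with adjusted p = 0.257 as the mean of its probe sets). With an estimated correlation, camera across all genes gave p = 0.74, 0.094 and 0.23, none adjusted. Few members were tested, and the imprinted genes that passed went both ways, so none of the 3 could be settled.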
